A study of Arabidopsis thaliana with 12 samples.

How the data were processed

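RNA from leaves and roots of 10-day-old seedlings was measured on 12 Affymetrix ATH1 arrays, 3 for each of WT leaves, pdx1.3 leaves, WT roots and pdx1.3 roots. Per the labels' protocols, biotin-labelled cRNA was made from 500 ng of total RNA. Groups and replicate numbers were taken from the sample titles, which the sample descriptions and the headers of the authors' table follow. The genotype entry among the characteristics reads the opposite for all 12 samples, and it was not used. Per the file headers, the authors summarised the scanned probes into a signal intensity per probe set with MAS5 in GCOS, whose versions are not given in the sources used here, and scaled each array to a 2% trimmed mean of 100.01, as checked on the values. These deposited intensities are linear, and each comes with the authors' call of present, marginal or absent. The authors also deposited a signed fold change (a ratio of means, or 2 to the mean of 9 pairwise log ratios), an unadjusted p-value on log2 signals, and the number of the 9 mutant and WT array pairs with a change call. The authors' quality block gives per array the background, the scaling factor, the percent of probe sets present and the 3'/5' ratios of actin and GAPDH. Percent present lay between 64.3 and 72.8, background between 36.13 and 50.76, and the scaling factor between 0.27 and 0.53.

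The per-array intensities were used as deposited, with no further normalization. The array has 22810 probe sets, of which 64 controls were left out and 22746 tested. Of these, 21646 name exactly 1 locus in the authors' table, 1095 several and 5 none, and no gene was named from a probe set with several. Symbols come from a gene table of the TAIR10.1 assembly, in which 21357 of the single-locus probe sets were found, and otherwise from the locus. Coordinates are not printed, because the files name no genome build. Intensities were deposited in 2 tables, 1 of them with more decimals, and rounding alone does not account for their differences: 26813 of 273720 values differed by more than 0.051, 20192 of them at signals below 1000, and the largest difference was 18.8. The files do not state which table the authors used. A constant of 16 was added to each signal before log2, so that changes of dim genes are understated, more so with a constant of 64. Limma 3.58.1 in R 4.3.3 fitted a mean per group over all 12 arrays with a variance trend. Each gene had the same variance in both organs. The p-values were adjusted by the Benjamini-Hochberg method over 22746 probe sets. A gene was called at an adjusted p under 0.05, and calls with at least 2-fold change were also counted. The contrasts were pdx1.3 minus WT in leaves and in roots, the difference of these (the interaction), and WT leaves minus WT roots. SE is the standard error of the fit, and SD that of the signals of 3 arrays.

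The signal of a probe set called absent on all arrays of a group is not told from background there. For such a gene the log2 change is given, and its size depends on the constant added before log2. The 25 gene lists (522 distinct loci) were fixed before the data were examined, as were the contrasts, the rule for named genes and the alternatives, unless said otherwise. Lists were tested with camera on 21439 genes, with the probe set of highest mean for each gene, a preset correlation of 0.01 and adjustment over the 25 lists. With an estimated correlation, 2 of the 9 lists that passed in roots held (sulphur and iron) and none of the 10 in leaves did. A list member counted as measured where a probe set names its locus alone.

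Named genes were PDX1.3 and, in each organ, the 8 largest rises and 8 largest falls among called probe sets with 1 locus, no overlap of the genotypes and a group mean above the array median. To these came the 3 members with the smallest p of each list that passed or had at least 3 called members, all members of the vitamin B6 list, and the 5 interaction genes with the smallest p in each direction. Of the genes that this rule gave, 1 was left out of the counts of named genes. The counts cover the others, but not all of these appear in the report: ACS8, YUC8, PIN4, GH3.6, GGT2 and THA1 were called in leaves, lost their calls in at least 1 fit without 1 array (highest adjusted p = 0.0619, 0.0595, 0.111, 0.0772, 0.0741 and 0.0985) and are not described there. Other list members in the text, such as NCED3, ABI1, HAI1, RD29B, DFR, NRT3.1 and, in leaves, AOS and SULTR2;1, were chosen after their values were seen, and each of these was called in all 12 fits that left out 1 array. Of the called named genes apart from PDX1.3, 41 of 50 in leaves, 19 of 29 in roots and 10 of 10 for the interaction were called in all 12 fits that left out 1 array.

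The alternatives were quantile normalization, centring each array on its median, constants of 1 and 64, a filter that kept 17059 probe sets, the signals of the other deposited table, a fit of only 1 organ, other variance models, stricter thresholds, the mean of a gene's probe sets, the replicate number as a block, and leaving out each array. After the data were seen, a filter on present calls (16873 probe sets), the actin 3'/5' ratio as a covariate and a fit without both leaf arrays numbered 1 were added. GO terms were not run, since no table used here assigns them to the probe sets.

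The fits were tested on simulated data with known changes, set on the log2 scale of signals with the constant already added. For dim genes such a fold stands for a larger change of the signal itself. The rates below therefore do not give the recovery of the same fold in the signal. The simulated noise was normal, with the same SD for a gene in all 4 groups, as the fit assumes. The rates of false calls thus do not test unequal spreads between groups or arrays that stand apart. In leaves 58% of genes changed 1.5-fold, 88.7% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 4.23% of calls false; in roots these were 57.1, 89.9 and 99.6%, with 5.58% false, over 22746 genes and 3 simulated sets. With lists shifted by 1 on the log2 scale, 3 of 3 were called in each organ and none of 72 others by camera, over 21439 genes. The simulated genes varied independently of each other, so this does not test camera on correlated genes. In the real data the estimated correlation in the photosynthesis list was 0.733. In a simulated overlap of 600 genes changed in both organs, 477 were called in both, 463 of them changed in both.

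The authors' deposited table states 537 higher and 317 lower probe sets in leaves and 156 and 162 in roots, at a fold of at least 2 and a change call in at least 7 of 9 pairs. That filter gave 538 and 317 in leaves and 156 and 162 in roots on the authors' deposited table, whose separate leaf list holds 717. Without controls 853 passed it in leaves, of which limma called 704, all in the same direction, and 318 in roots, of which limma called 138. The authors' deposited unadjusted p-values lay under 0.05 for 2560 probe sets in leaves and 1053 in roots; after Benjamini-Hochberg adjustment none did in either organ, against 1650 and 184 by limma. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 prepared tables and figures.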

Results

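Transcript levels were measured in leaves and roots of Arabidopsis thaliana seedlings, in the Col-0 wild type (WT) and in a knockout of PDX1.3, which encodes a catalytic subunit of the enzyme that makes vitamin B6 de novo. The seedlings had grown for 10 days on a medium with 1% sucrose and no vitamin B6, in 16 h light and 8 h darkness at 22 and 18 °C. Each of the 12 samples was hybridised to its own Affymetrix ATH1 array, a 1-colour array on which a set of short probes reports each gene. The 4 groups of 3 arrays are described by the series design as biological replicates, and this number of arrays limits the precision. The arrays were scaled to a common trimmed mean of 100.01, and the authors' deposited quality values listed 64.3 to 72.8% of probe sets as present per array. The actin 3'/5' ratio, a measure of RNA integrity that is lower for intact RNA, lay at 8.27, 6.76 and 5.6 in WT leaves, 3.12, 5.94 and 8.71 in pdx1.3 leaves, 4.9, 4.45 and 6.4 in WT roots, and 2.97, 3.99 and 6.59 in pdx1.3 roots, per the authors' deposited table. Replicates of a group correlated across genes at r = 0.940 to 0.989, and genes are not independent replicates. In a principal component analysis, component 1 (90.4% of the variance) parted leaves from roots, and component 2 (3.7%) parted the genotypes in leaves. WT leaves replicate 1 stood apart on component 2 at -38.25, against -16.08 and -14.49 for the other WT leaf arrays. On the other side pdx1.3 leaves replicate 1 lay at 31.04, against 17.82 and 16.83 for the other pdx1.3 leaf arrays.

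The knocked-out gene was examined first, since it checks the labels. The sample titles and descriptions gave the groups used here, while the genotype entry among the characteristics read the opposite for all 12 samples. PDX1.3 (AT5G01410) gave a signal of 43.1 ± 6.54 (SD, n = 3) in the leaf samples titled as knockout and 823 ± 201 (SD, n = 3) in WT leaves, a log2 change of -3.80 (SE 0.18, adjusted p = 7.28e-07). In roots the signals were 97.9 ± 16.9 (SD, n = 3) and 276 ± 10.5 (SD, n = 3), a log2 change of -1.37 (SE 0.18, adjusted p = 0.00238). The fall was larger in leaves than in roots (interaction log2 -2.43, adjusted p = 0.000654). PDX1.3 was called present on all 12 arrays. The position of its probe set relative to the mutation is not given in the sources used here, so the signal left in the mutant is not evidence of a working transcript. Of the 5 other measured genes of vitamin B6 metabolism, none was called by limma in either organ. In leaves PDX3 and PLR1 had log2 changes of 0.37 (adjusted p = 0.158) and 0.33 (adjusted p = 0.197), PDX2 of 0.21 (adjusted p = 0.470), PDX1.2 of 0.13 (adjusted p = 0.790) and SOS4 of -0.14 (adjusted p = 0.522). Without WT leaves replicate 1 these were 0.18 for PLR1, -0.0547 for PDX1.2 and -0.0857 for SOS4, without pdx1.3 leaves replicate 3 0.1175 for PDX2 and 0.26 for PDX1.2, and PDX1.2 had -0.0544 without pdx1.3 leaves replicate 1 and 0.28 without WT leaves replicate 2. In roots the log2 changes ran from -0.15 for SOS4 to 0.09 for PDX1.2, and from -0.23 (PDX2) to 0.19 (PDX1.2) in the fits without 1 array. PDX1.1 has no probe set of its own and was not analysed here.

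**Figure D1:**
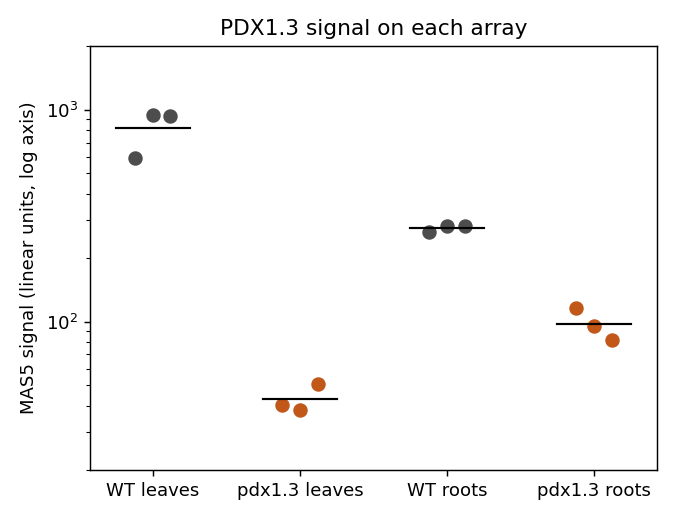
PDX1.3 signal (linear MAS5 units, on a log axis) on each of the 12 arrays, by group; points are arrays and horizontal lines are the means of 3 arrays. The pdx1.3 leaf arrays lie between 38.2 and 50.5 and the WT leaf arrays between 591 and 942.

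The comparison of pdx1.3 with WT leaves asked which transcripts differ in a green organ between the mutant and WT. The arrays hold only this mutant and WT, with no other mutant line and no rescue. Loss of PDX1.3 therefore cannot be told apart from other differences between the lines, here and in roots. Of the measured genes that respond to abscisic acid (ABA), drought and cold 16 of 19 rose, and of the jasmonate genes 9 of 16, and neither list passed with an estimated correlation (adjusted p = 0.139 with an estimated correlation for each). RAB18, a dehydrin of the ABA list, had a signal of 739 ± 228 (SD, n = 3) in the mutant and 81.5 ± 41.7 (SD, n = 3) in WT, a log2 change of 3.00 (SE 0.29, adjusted p = 0.000107). MYC2, a transcription factor of jasmonate signalling, rose by 1.91 on the log2 scale. MIOX2, an inositol oxygenase, had a signal of 45.9 ± 13.7 (SD, n = 3) against 660 ± 136 (SD, n = 3) and fell by 3.45 on the log2 scale (adjusted p = 2.32e-06). XTH15, a cell wall xyloglucan enzyme, had 18.4 ± 3.73 (SD, n = 3) against 366 ± 140 (SD, n = 3) and fell by 3.42 (adjusted p = 6.42e-06). Of the genes induced by low oxygen 6 of 12 fell, of the sugar starvation genes 5 of 11 and of the ethylene genes 5 of 25 (adjusted p = 0.288, 0.139 and 0.561 with an estimated correlation).

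Among the genes with the largest rises in leaves were LEA7, a late embryogenesis abundant protein (3.04), the ABA-responsive AT3G02480 (2.70), AT3G28270 (2.61) and the transcription factor NAC019 (2.55). MYB47, a transcription factor, was called absent on all 3 WT leaf arrays. With the added constant it had a log2 change of 2.62 (adjusted p = 3.79e-06). LTP4, a lipid transfer protein (2.85), and PUB19, a ubiquitin ligase (2.61), also rose. The call of LTP4 ended without pdx1.3 leaves replicate 2 (adjusted p = 0.0681), WT leaves replicate 1 (adjusted p = 0.0546) or WT leaves replicate 2 (adjusted p = 0.0696), and that of PUB19 without pdx1.3 leaves replicate 2 (adjusted p = 0.0507) or 3 (adjusted p = 0.0525). The largest falls included the chitinase AT2G43620 (-3.79), the lipid transfer family members AT4G22470 (-3.35), EARLI1 (-2.70) and AZI1 (-2.60), and the oxidoreductase AT2G36690 (-2.79). In these 5 genes WT leaves replicate 1 was the brightest array, so that the WT signal of AT2G43620 was 1210 ± 1684 (SD, n = 3), and each call held without that array. Without both leaf arrays numbered 1 EARLI1 had a log2 change of -1.78.

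Of the 19 measured genes of the ABA, drought and cold list, 16 rose and 1 fell, and 18 passed when adjusted over the list alone. The median log2 change was 1.71 (camera adjusted p = 1.07e-15), and the list did not pass with an estimated correlation between genes (adjusted p = 0.139 with an estimated correlation). NCED3, a rate-limiting enzyme of ABA synthesis, rose by 2.07 (adjusted p = 0.000144). ABI1 (1.73) and HAI1 (2.33), protein phosphatases that restrain ABA signalling, RD29B (2.52) and the transcription factor ABF3 (1.32, adjusted p = 9.70e-05) rose too. The member that fell was PRODH1, which breaks down proline (-2.22, adjusted p = 0.000101). In the jasmonate and wounding list 9 of 16 measured genes rose, and 11 passed when adjusted over the list alone. Its median was 1.196 (camera adjusted p = 2.22e-10, adjusted p = 0.139 with an estimated correlation). JAZ9, a repressor of jasmonate signalling, rose by 1.62, AOS, an enzyme of jasmonate synthesis, by 1.47, and JAR1, which conjugates jasmonate, by 0.91.

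In the flavonoid and anthocyanin list 7 of 21 measured genes rose, with a median of 0.46, and adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 0.000593, adjusted p = 0.288 with an estimated correlation). The transcription factor PAP1 and the glycosyltransferase UF3GT were called absent on all 3 WT leaf arrays. With the added constant they had log2 changes of 1.07 and 0.94. DFR, an enzyme of anthocyanin synthesis, rose by 1.57 (adjusted p = 0.00699). In the glucosinolate list MYB34 (1.21) and FMOGSOX1 (0.71) rose out of 26 measured genes. Its median was 0.63, and adjusted over the list alone 6 rose and 3 fell (camera adjusted p = 0.00447, adjusted p = 0.562 with an estimated correlation). Without WT leaves replicate 1 the median was 0.37, and FMOGSOX1 lost its call without both leaf arrays numbered 1 (adjusted p = 0.0551). MYB51, another regulator of this pathway, had a log2 change of -0.95 (adjusted p = 0.0574), and was called without pdx1.3 roots replicate 3 (adjusted p = 0.0357) or WT roots replicate 1 (adjusted p = 0.0309).

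The hypoxia list was lower in pdx1.3 leaves: 6 of 12 measured genes fell, 7 when adjusted over the list alone, with a median of -0.57 (camera adjusted p = 1.2e-07, adjusted p = 0.288 with an estimated correlation). HB1, a haemoglobin, had a log2 change of -2.54 and LBD41, a transcription factor, of -1.78. PCO1, a cysteine oxidase, was called absent on all 3 pdx1.3 leaf arrays, and with the added constant had a log2 change of -1.82. Of the 11 measured genes of the sugar starvation and senescence list 5 fell, 6 when adjusted over the list alone, with a median of -0.73 (camera adjusted p = 0.000532, adjusted p = 0.139 with an estimated correlation). They included PRODH1, which is in both lists, and DIN10 (-1.08), as well as EXO (-1.57), whose call ended without pdx1.3 leaves replicate 2 (adjusted p = 0.0556) or WT leaves replicate 2 (adjusted p = 0.0525). In the ethylene list 5 of 25 measured genes fell. Adjusted over the list alone 1 rose and 7 fell, with a median of -0.20 (camera adjusted p = 0.00447, adjusted p = 0.561 with an estimated correlation). The median was -0.12 without pdx1.3 leaves replicate 1, -0.0541 without WT leaves replicate 1, -0.33 without WT leaves replicate 3 and -0.11 with the actin covariate. ACS7, of ethylene precursor synthesis, had a log2 change of -2.05.

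For nitrate and ammonium uptake and assimilation 1 of 27 measured genes rose and 4 fell, and 3 and 6 when adjusted over the list alone. The ammonium transporter AMT1;2 rose by 1.73 (1.0975 without both leaf arrays numbered 1), while the nitrate transporter NRT1.1 (-1.25), NRT3.1, a partner of high-affinity nitrate transporters (-2.13, adjusted p = 0.0132, and -1.39 without WT leaves replicate 1), and the nitrate reductase NIA1 (-1.11) fell. In the phosphate starvation list 1 of 16 measured genes rose and 3 fell, the same counts as adjusted over the list alone. The galactolipid synthase MGD2 (-0.95) and the phospholipase PLDZ2 (-0.68) fell, and the transporter G3PP1 rose (0.78). Both lists stood at medians of -0.20 (camera adjusted p = 0.0452), with adjusted p = 0.288 and adjusted p = 0.562 with an estimated correlation. Without WT leaves replicate 1 the medians were -0.0504 and -0.12, without WT leaves replicate 2 that of the nitrate list was -0.11, and without pdx1.3 leaves replicate 2 that of the phosphate list was -0.0674. The nitrate list lost its call without pdx1.3 leaves replicate 1 (adjusted p = 0.0651) or 2 (adjusted p = 0.0638), and under quantile normalization (adjusted p = 0.161), centring (0.0758), a constant of 64 (0.0570) and the actin covariate (0.0722). The phosphate list lost it without pdx1.3 leaves replicate 2 (adjusted p = 0.455) or WT leaves replicate 2 (adjusted p = 0.135), and under quantile normalization (adjusted p = 0.104), centring (0.0838), a constant of 64 (0.0570), the actin covariate (0.0616), the filter on dim probe sets (0.0530) and the filter on present calls (0.0752). The photosynthesis list had a median of -0.21 (camera adjusted p = 0.00396, adjusted p = 0.739 with an estimated correlation). None of its 33 measured genes passed by limma, over all genes or adjusted over the list alone. It lost its call without WT leaves replicate 2 (adjusted p = 0.0801) and under quantile normalization (adjusted p = 0.820), and its median was -0.13 with the actin covariate.

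The other 15 lists did not pass in leaves, with camera adjusted p from 0.0746 for sulphur assimilation to 0.846. Of the 13 measured circadian clock genes 4 rose and 2 fell, the same counts as adjusted over the list alone (median 0.26, camera adjusted p = 0.0788). The list passed without pdx1.3 leaves replicate 1 (adjusted p = 0.0482) or WT leaves replicate 1 (adjusted p = 0.0420), and its median was 0.1363 without WT leaves replicate 2. PRR9 (1.34), of the clock's morning loop, and RVE1 (1.91), a transcription factor, rose. In the sulphur list 2 of 16 rose and 3 when adjusted over the list alone, including the sulphate transporter SULTR2;1 (1.295). That list passed without pdx1.3 leaves replicate 2 (adjusted p = 0.0174) or WT leaves replicate 1 (adjusted p = 0.0199). Of the 50 measured enzymes that use pyridoxal phosphate, the active form of vitamin B6, 3 rose and 1 fell, and 5 and 3 when adjusted over the list alone. ADC1, an arginine decarboxylase, rose by 0.90 (adjusted p = 0.0114). The median of that list was 0.03 and its test pointed down (camera adjusted p = 0.846). For auxin synthesis and transport 1 of 26 rose and 2 fell, and for auxin response 2 of 22 rose and 2 fell. YUC5 had a log2 change of -1.15, IAA19 of -0.95 and IAA14 of 1.38. Adjusted over the list alone the auxin counts were 2 and 3 in both lists. In the iron list 1 of 16 rose and 1 fell, and 1 of 16 cytokinin response genes and 1 of 15 markers of root stele, endodermis and tip rose. No gene of the oxidative stress, heat shock, chlorophyll and haem, salicylate, cell cycle or root hair lists passed by limma. Camera called the cytokinin and the chlorophyll lists without WT leaves replicate 1 (adjusted p = 0.0145 and 0.0457), and the cell cycle list without pdx1.3 leaves replicate 3 (adjusted p = 0.0209) or WT leaves replicate 2 (adjusted p = 0.0420). In the vitamin B6 list the median was 0.17, while the mean (-0.48) and the test (camera adjusted p = 0.704) pointed down, since PDX1.3 is a member. The median was 0.0943 without pdx1.3 leaves replicate 1 and 0.0618 without WT leaves replicate 1.

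Across all genes limma called 1650 of 22746 probe sets in leaves (7.25%), of which 1075 were higher and 575 lower in pdx1.3, and 480 changed at least 2-fold (291 higher, 189 lower). In 1641 of the 1650 the signals of the 2 genotypes did not overlap, as they did not in 24.1% of all probe sets, where chance gives 10% for 3 against 3. The share of higher calls followed the scaling: it was 65.2% as deposited, 58.4% after quantile normalization (940 higher, 670 lower) and 50.1% with each array centred on its median (838 higher, 835 lower). The count was 1053 without pdx1.3 leaves replicate 2, 976 with the replicate number as a block, and 515 with only the 6 leaf arrays in the fit, where 39 of the 79 named genes called in leaves or roots lost their calls.

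The same comparison in roots asked which transcripts change in the organ that grows in the medium without vitamin B6. Genes of the marneral cluster, neighbouring genes for a root triterpene, rose. MRN1 (AT5G42600), the marneral synthase, was called absent on all 3 WT root arrays and had a signal of 413 ± 142 (SD, n = 3) in the mutant. With the constant of 16 it rose by 4.40 on the log2 scale (adjusted p = 6.89e-07). Its neighbours CYP705A12 and CYP71A16 rose by 2.79 (SE 0.17) and 2.44 (SE 0.22). The thalianol genes THAS1 (1.89), THAD (1.67) and THAH (1.35), a related cluster, rose as well. QQS, an orphan gene that affects starch, had a signal of 15.3 ± 4.35 (SD, n = 3) against 180 ± 47.2 (SD, n = 3) and fell by 2.63 on the log2 scale (adjusted p = 1.28e-05). Of the sulphur and the jasmonate genes 3 of 16 each rose, and of the iron deficiency genes 4 of 16 and of the photosynthesis genes 1 of 33 fell. The sulphur and iron lists passed with an estimated correlation (adjusted p = 0.0473 and 0.0447 with an estimated correlation), and the jasmonate and photosynthesis lists did not (adjusted p = 0.0819 and 0.103 with an estimated correlation).

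Further rises in roots were those of AT5G04120, a phosphoglycerate mutase family member (3.85, adjusted p = 1.86e-05), AT5G41280 (2.41) and ARD3 of the methionine salvage pathway (2.38, signal 808 ± 191 against 141 ± 30.5, SD, n = 3). JRG21, an oxidoreductase, was called absent on all 3 WT root arrays, and with the added constant had a log2 change of 2.69. The peroxidase AT1G49570 rose by 1.97. The falls included the chitinases AT2G43590 (-2.44) and AT2G43570 (-1.96), the malate transporter ALMT1 (-2.22), the lectin AT3G16530 (-1.95), the pathogenesis-related AT4G07820 (-1.91), the peroxidase PER4 (-1.91) and the lipid transfer protein DIR1 (-1.75). The calls of AT1G49570, ALMT1, AT3G16530 and PER4 ended without pdx1.3 roots replicate 1 (adjusted p = 0.0638, 0.145, 0.207 and 0.0790) and without replicate 2 (0.0536, 0.0813, 0.195 and 0.0694). That of PER4 also ended without WT roots replicate 2 (adjusted p = 0.0703), and those of ALMT1 and AT3G16530 without WT roots replicate 1 (adjusted p = 0.0625 and 0.0744), 2 (0.104 and 0.183) or 3 (0.0824 and 0.162). AT3G16530 lost its call in 4 fits without a leaf array too, those without pdx1.3 leaves replicates 2 and 3 (adjusted p = 0.0679 and 0.0695) and WT leaves replicates 2 and 3 (adjusted p = 0.0558 and 0.0709).

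On component 2, pdx1.3 roots replicate 3 lay at -0.81, apart from replicates 1 and 2 at 9.71 and 10.81 and close to WT roots replicate 3 at -1.26. The photosynthesis list was lower in pdx1.3 roots, with a median of -0.64 over 33 measured genes (camera adjusted p = 1.24e-36, adjusted p = 0.103 with an estimated correlation). Over all genes only LHCB5, a light-harvesting protein, was called (-1.04, adjusted p = 0.0231), and adjusted over the list alone 28 genes were, all lower. LHCB5 lost its call without any of 5 of the 6 root arrays: pdx1.3 roots replicates 1 (adjusted p = 0.155) and 2 (adjusted p = 0.128) and WT roots replicates 1, 2 and 3 (adjusted p = 0.0785, 0.0564 and 0.0990). PSAG and LHCB3 had log2 changes of -1.28 (adjusted p = 0.0550) and -0.97 (adjusted p = 0.0661). Without pdx1.3 roots replicate 3 both were called (adjusted p = 0.00112 and 0.00941), as was LHCB3 without WT leaves replicate 1 (adjusted p = 0.0425). The WT root signals of the list were a median of 2.91% of those in WT leaves. Relative to the WT root mean, the list medians of pdx1.3 roots replicates 1 and 2 were -0.776 and -0.983, and that of replicate 3 was -0.219, close to WT roots replicate 1 at -0.208. The chlorophyll and haem list had a median of -0.12 over 21 measured genes (camera adjusted p = 0.000272, adjusted p = 0.374 with an estimated correlation), and of -0.20 without WT roots replicate 1. No member passed by limma, and 3 were lower when adjusted over the list alone. Among them CRD1 had a log2 change of -0.72 (adjusted p = 0.0811), and was called without WT roots replicate 1 (adjusted p = 0.0189).

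In the sulphur assimilation list 3 of 16 measured genes rose, and 8 when adjusted over the list alone, with a median of 0.61 (camera adjusted p = 7.4e-10, adjusted p = 0.0473 with an estimated correlation). SULTR2;1, a sulphate transporter, rose by 1.58, GGCT2;1, which degrades glutathione, by 1.52 and SDI1, a gene of sulphur deficiency, by 1.51. SDI1 lost its call without pdx1.3 leaves replicate 3 (adjusted p = 0.0534), pdx1.3 roots replicates 1 and 2 (adjusted p = 0.155 and 0.131) and WT roots replicates 2 and 3 (adjusted p = 0.0934 and 0.118). Of the 16 measured iron deficiency genes 4 fell, and 8 when adjusted over the list alone, with a median of -0.37 (camera adjusted p = 6.35e-09, adjusted p = 0.0447 with an estimated correlation). F6H1, an enzyme of coumarin synthesis, had a log2 change of -0.84 (adjusted p = 0.0063, and 0.195 with a constant of 1 in place of 16), the iron transporter IRT1 of -0.95 and NAS2, a nicotianamine synthase, of -0.82. IRT1 and NAS2 lost their calls without pdx1.3 roots replicate 1 (adjusted p = 0.141 and 0.145) or 2 (0.112 and 0.123) and WT roots replicate 1 (adjusted p = 0.0785 and 0.107) or 2 (0.115 and 0.0904). For jasmonate and wounding 3 of 16 measured genes rose, and 7 when adjusted over the list alone, with a median of 0.77 (camera adjusted p = 1.87e-10, adjusted p = 0.0819 with an estimated correlation). The repressor JAZ10 rose by 1.60 (adjusted p = 0.00118), TAT3, a tyrosine aminotransferase, by 1.43 (adjusted p = 0.0262) and AOS, an enzyme of jasmonate synthesis, by 1.05 (adjusted p = 0.045). TAT3 lost its call without pdx1.3 roots replicates 1 and 3 (adjusted p = 0.152 and 0.0552) and WT roots replicates 1, 2 and 3 (adjusted p = 0.112, 0.0938 and 0.0581). AOS lost its call in roots without pdx1.3 roots replicates 1 and 2 (adjusted p = 0.207 each), WT roots replicates 1 and 3 (adjusted p = 0.138 and 0.118), pdx1.3 leaves replicates 1, 2 and 3 (adjusted p = 0.0598, 0.071 and 0.0741) and WT leaves replicates 2 and 3 (adjusted p = 0.0747 and 0.0636).

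In the list of markers of root stele, endodermis and tip 3 of 15 measured genes rose, and 5 when adjusted over the list alone (median 0.10, camera adjusted p = 0.000613, adjusted p = 0.103 with an estimated correlation). Its median was 0.0531 without pdx1.3 roots replicate 2 and 0.17 without WT roots replicate 3. All 3 were the thalianol genes THAS1, THAD and THAH, and with a constant of 1 in place of 16 added to the signals their adjusted p were 0.0511, 0.173 and 0.0531, and that of CYP71A16 was 0.0511. The cytokinin response list had a median of -0.15 (camera adjusted p = 0.00223, adjusted p = 0.328 with an estimated correlation) and lost its call without WT roots replicate 1 (adjusted p = 0.0592). The phosphate starvation list had a median of 0.22 (camera adjusted p = 0.00511, adjusted p = 0.38 with an estimated correlation) and lost its call without pdx1.3 roots replicate 3 (adjusted p = 0.175) or WT roots replicate 3 (adjusted p = 0.316). No member of either list passed by limma, over all genes or adjusted over the list alone. The vitamin B6 list (median -0.07, camera adjusted p = 0.0211, adjusted p = 0.27 with an estimated correlation) had PDX1.3 as its only gene that passed, and lost its call without pdx1.3 roots replicate 3 (adjusted p = 0.118) or WT roots replicate 3 (adjusted p = 0.0715). Its median was -0.13 without pdx1.3 roots replicate 2 or WT roots replicate 1 and -0.0346 without pdx1.3 roots replicate 3. The other 16 lists did not pass in roots. Without 1 array some did: auxin synthesis without WT roots replicate 3 (adjusted p = 0.0267), auxin response without pdx1.3 roots replicate 2 (0.0324) or WT roots replicate 1 (0.00218), oxidative stress without pdx1.3 roots replicate 3 (0.00327), flavonoids without pdx1.3 roots replicate 1 (0.00721) or 2 (0.00945) or WT leaves replicate 3 (0.0394), hypoxia without pdx1.3 roots replicate 3 (0.0231) or WT roots replicate 1 (0.0212), sugar starvation without WT roots replicate 1 (0.0212), and root hairs without WT roots replicate 1 (0.00134) or 3 (1.64e-09). None of the 19 measured ABA genes passed by limma (median 0.07, camera adjusted p = 0.691), nor did any of the hypoxia, flavonoid or pyridoxal phosphate enzyme lists. Of the remaining lists only 3 had a gene that passed by limma, each with 1: a member of the nitrate list and DIN10 of the sugar starvation list (-1.46) fell, and a member of the salicylate list rose. The nitrate member lost its call without pdx1.3 roots replicate 1 (adjusted p = 0.145) or 2 (0.0816) and WT roots replicate 1 (0.0736), 2 (0.0664) or 3 (0.0887), and the salicylate member without pdx1.3 roots replicate 1 (adjusted p = 0.0579) or 2 (0.0545).

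Across all genes limma called 184 of 22746 probe sets in roots (0.81%), 113 higher and 71 lower in pdx1.3, of which 101 changed at least 2-fold (67 higher, 34 lower). None of the 184 overlapped between the genotypes, which held for 10.7% of all probe sets where chance gives 10%. The count moved with single arrays: it was 75 without pdx1.3 roots replicate 1, 102 without pdx1.3 roots replicate 2, 385 without pdx1.3 roots replicate 3 and 96 without WT roots replicate 2. It was 78 with a constant of 1 in place of 16, where 17 of the 89 named genes called in any comparison lost their calls, 90 with the replicate number as a block and 61 with only the 6 root arrays in the fit.

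**Figure D2:**
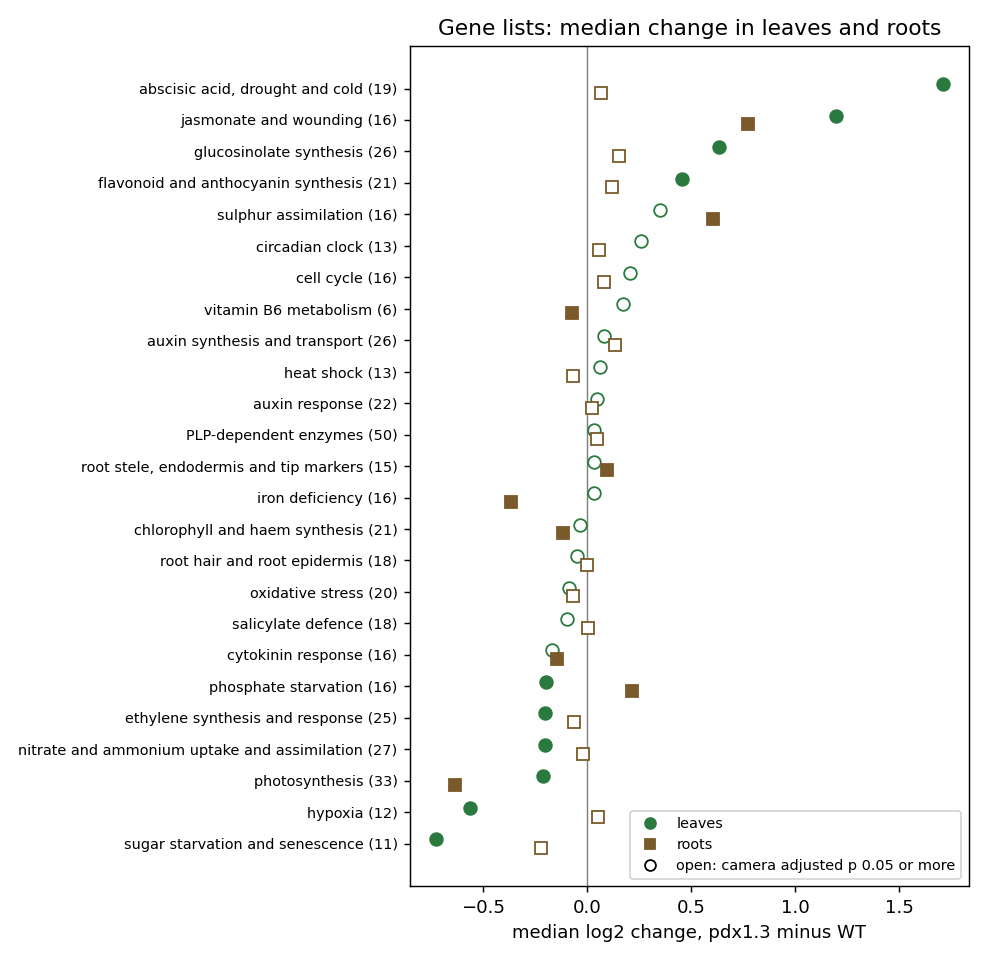
Median log2 change, pdx1.3 minus WT, of the measured genes of 25 lists (number measured in brackets), in leaves (circles) and roots (squares); filled symbols had a camera adjusted p under 0.05 with the preset correlation. The ABA, drought and cold list lies at 1.71 in leaves and 0.07 in roots, and the photosynthesis list at -0.21 and -0.64.

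The leaf and root changes were then compared with each other. Some genes changed the same way in both organs: QQS fell by 2.16 in leaves and by 2.63 in roots, and DIN10, a dark-induced gene of sugar metabolism, by 1.08 and by 1.46. SULTR2;1 rose by 1.295 and 1.58. ARD3 went the opposite way in the organs, at -0.83 in leaves (adjusted p = 0.0258) and 2.38 in roots. Its leaf call ended without pdx1.3 leaves replicate 2 (adjusted p = 0.0795) or 3 (adjusted p = 0.0799) and WT leaves replicate 1 (adjusted p = 0.0504) or 3 (adjusted p = 0.0913). Of the genes called in both organs 16 rose in both, where independent lists would give 5.34 (Fisher's exact test, two-sided p = 8.22e-05), and 9 fell in both against 1.79 (Fisher's exact test, two-sided p = 7.31e-05). The fit gives each gene the same variance in both organs, so the lists are not independent and these p-values can be too small. The 9 falls include PDX1.3, whose fall the knockout gives, and without it, a test chosen after the results were seen, 8 fell in both against 1.77 (Fisher's exact test, two-sided p = 0.000374). None rose in leaves and fell in roots against 3.36 (Fisher's exact test, two-sided p = 0.082), and 2, ARD3 and AT1G22550, fell in leaves and rose in roots against 2.86 (Fisher's exact test, two-sided p = 1). AT1G22550, a peptide transporter family member named after its values were seen, had log2 changes of -0.67 and 0.71, and its root call ended without pdx1.3 roots replicate 1 (adjusted p = 0.0598) or 2 (adjusted p = 0.0816) and WT roots replicate 1 (adjusted p = 0.0581) or 2 (adjusted p = 0.0892). Across genes, which are not independent replicates, the leaf and root changes correlated at r = 0.218. The 25 shared calls were 5 without pdx1.3 roots replicate 1, 9 without WT roots replicate 2, 11 without pdx1.3 leaves replicate 2, 15 without pdx1.3 roots replicate 2, and 12 without pdx1.3 leaves replicate 3, WT leaves replicate 2, WT roots replicate 1 or WT roots replicate 3, and 47 without pdx1.3 roots replicate 3.

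The interaction test asked which genes changed differently in the organs. MRN1 had no signal above absence in leaves of either genotype, and its change differed by -4.40 (adjusted p = 4.36e-05). ARD3 differed by -3.21 (adjusted p = 0.000297). MIOX2 (-3.29), XTH15 (-3.60) and the receptor-like kinase CRK30 (-2.34, adjusted p = 6.3e-05) fell in leaves, and in roots their log2 changes were -0.16 (adjusted p = 1), 0.18 (adjusted p = 1) and -0.06 (adjusted p = 1). The desaturase ADS1 (1.49), the lectin AT1G52000 (2.34), MYB47 (2.19) and the transcription factor NIG1 (0.78) rose in leaves, and the chitinase AT2G43570 (2.69) fell in roots. MYB47, AT1G52000 and NIG1 were called absent on all 6 root arrays, CRK30 on 5 of them, and NIG1 was called present on 2 of the 3 pdx1.3 leaf arrays. Limma called 429 probe sets, 258 with the higher change in leaves and 171 with the higher change in roots, a share of 60.1% as deposited and 51.9% with centred arrays. Among the 25 lists 11 differed, of which ABA, drought and cold had the highest median difference (1.703, camera adjusted p = 4.46e-15, adjusted p = 0.272 with an estimated correlation) and hypoxia the lowest (-0.73, camera adjusted p = 3.35e-08, adjusted p = 0.353 with an estimated correlation). The count of 429 was 266 without pdx1.3 leaves replicate 2, 274 without pdx1.3 leaves replicate 3, 178 and 200 without pdx1.3 roots replicates 1 and 2, 272 without WT leaves replicate 2, 137 and 247 without WT roots replicates 2 and 3, 134 with the replicate number as a block and 248 with a constant of 1 in place of 16, where MYB47 was not called (adjusted p = 0.241).

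**Figure D3:**
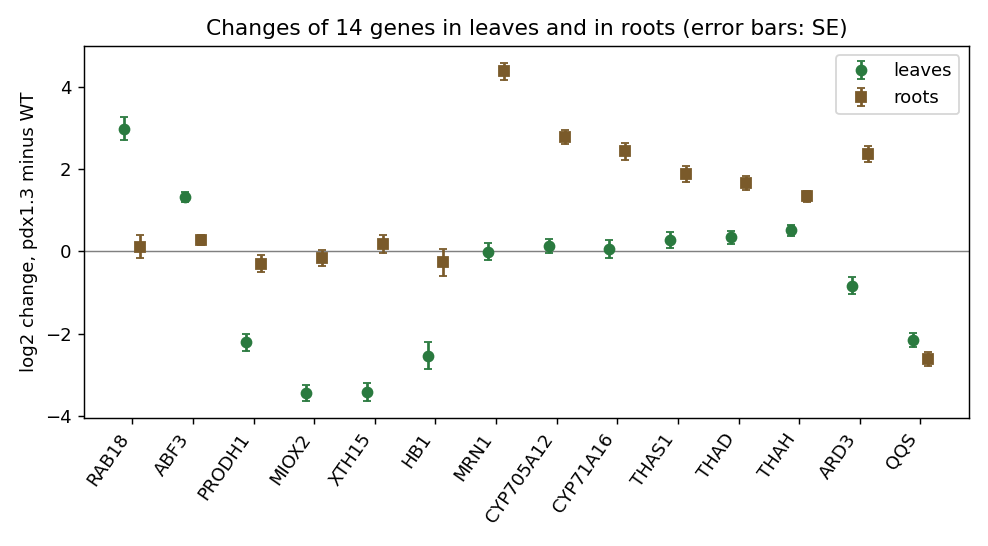
Log2 change, pdx1.3 minus WT, of 14 genes in leaves (circles) and roots (squares), with bars for the standard error of the fit over 12 arrays. RAB18 lies at 3.00 in leaves and 0.12 in roots and CYP705A12 at 0.13 and 2.79; MRN1 was called absent on all WT root arrays, so its height depends on the constant of 16 added to the signals.

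The organs of the WT were compared to place these changes. All 33 measured photosynthesis genes were higher in leaves, with a median log2 difference of 5.03 (camera adjusted p = 3.59e-27, adjusted p = 0.203 with an estimated correlation), as were 19 of 21 chlorophyll and haem genes (median 3.15, camera adjusted p = 5.43e-14, adjusted p = 0.119 with an estimated correlation). All 18 root hair genes were higher in roots (median -3.32, camera adjusted p = 1.18e-09, adjusted p = 0.332 with an estimated correlation), as were 13 of 15 markers of root stele, endodermis and tip (median -2.93, camera adjusted p = 2.34e-07, adjusted p = 0.081 with an estimated correlation). So were all 12 hypoxia genes (median -3.41, camera adjusted p = 1.76e-08, adjusted p = 0.213 with an estimated correlation) and all 16 cell cycle genes (median -1.05, camera adjusted p = 4.7e-05, adjusted p = 0.371 with an estimated correlation). The sugar starvation list was higher in leaves (8 of 11 higher, median 1.56, camera adjusted p = 0.000963, adjusted p = 0.195 with an estimated correlation), as was that of pyridoxal phosphate enzymes (23 of 50 higher and 12 lower, median 0.31, camera adjusted p = 0.0135, adjusted p = 0.592 with an estimated correlation). Limma called 11949 of 22746 probe sets (52.53%), 4747 higher in leaves and 7202 higher in roots, and with each array centred on its median 7913 and 5780. Centring moved the median difference of all genes from -0.048 to 0.119, so the numbers of calls in each direction are relative to the scaling.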

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

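The tests of shoot tissue and of other groupings of the arrays were planned before the results were seen, and the tests of scaling, RNA quality, WT leaves replicate 1, time of harvest and thalianol signal were chosen after. The interaction test picked out 43 of the 102 named genes, whose change differed between leaves and roots. Over all probe sets it called 1.89%. Some of the 102 were named for their interaction or for a large change in 1 organ, so the share among them is raised by that choice. The values are leaf minus root log2 changes, and where a group was called absent they depend on the constant of 16. The change was higher in leaves for RAB18 (2.88), AT2G43570 (2.69), AT1G52000 (2.34), MYB47 (2.19), AT4G07820 (1.69), ADS1 (1.49), PRR9 (1.47), JAZ9 (1.25), IAA14 (1.23), MYB34 (1.22), ABF3 (1.04), PAP1 (0.95), NAS2 (0.93), JAR1 (0.92), F6H1 (0.89), NIG1 (0.78) and PAP2 (0.66). It was lower in leaves for MRN1 (-4.40), AT5G04120 (-3.82), XTH15 (-3.60), MIOX2 (-3.29), ARD3 (-3.21), CYP705A12 (-2.67), PDX1.3 (-2.43), AT5G41280 (-2.40), CYP71A16 (-2.37), CRK30 (-2.34), HB1 (-2.27), AT1G49570 (-2.23), JRG21 (-2.09), ACS7 (-2.01), LBD41 (-1.93), PRODH1 (-1.92), PCO1 (-1.68), GGCT2;1 (-1.62), THAS1 (-1.60), JAZ10 (-1.59), THAD (-1.33), IAA19 (-1.32), MGD3 (-1.23), MGD2 (-1.20), PLDZ2 (-1.10) and THAH (-0.83). Of the 25 lists 11 differed, with medians of 1.703 for ABA, drought and cold, 0.63 for jasmonate, 0.46 for photosynthesis, 0.39 for glucosinolates, 0.36 for iron, 0.27 for flavonoids, -0.21 for sulphur, -0.26 for sugar starvation, -0.29 for phosphate, -0.40 for ethylene and -0.73 for hypoxia; none of the 11 passed with an estimated correlation.

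The photosynthesis list was lower in pdx1.3 roots (median log2 -0.64, adjusted p = 0.103 with an estimated correlation), though pdx1.3 roots replicate 3 (-0.219) lay near WT roots replicate 1 (-0.208). Scaling of the arrays was argued against, since the list median stayed at -0.6532 or lower after quantile normalization and after centring. Shoot tissue in the root samples could not be decided: only 2 of the 14 measured shoot markers were bright, with WT root signals of 0.54% (ESM1) and 2.99% (LTP1) of those in WT leaves, a median of 1.77%, against 2.91% for the photosynthesis genes. These 2 changed by a median of -0.026 in roots. The actin 3'/5' ratio was 2.97 and 3.99 in pdx1.3 roots replicates 1 and 2 and 6.59 in replicate 3, and 4.9, 4.45 and 6.4 in WT roots. With the actin ratio as a covariate the list kept its camera call with the preset correlation. RNA quality was not weighed further as a cause of this fall. Shoot tissue, RNA quality and a difference between the genotypes in root plastids therefore all stay open.

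The ABA, drought and cold list was higher in pdx1.3 leaves (median log2 1.71, adjusted p = 0.139 with an estimated correlation). Neither RNA quality nor WT leaves replicate 1, which stood apart, accounts for it as the whole cause: the median was 1.6264 with the actin 3'/5' ratio as a covariate and 1.4353 without that array, and the list passed camera with the preset correlation both times. Time of harvest cannot be told apart from genotype, because the labels give no hour of harvest. Clock genes that peak in the morning had a median change of 0.905 and those that peak in the evening of 0.121, a difference of 0.784. The called ones parted by time of peak. Of the morning genes CCA1 (0.90), PRR9 (1.34), RVE8 (0.62) and RVE1 (1.91) rose, and of the evening genes CCR2 (-1.08) and CCR1 (-0.79) fell. LHY, TOC1, GI, ELF4 and ELF3 were not called. A difference in water status of the seedlings was not tested. A response of the mutant leaves to ABA stays a hypothesis.

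The marneral genes MRN1, CYP705A12 and CYP71A16 rose in pdx1.3 roots. Signal from the related thalianol genes was argued against for MRN1 and CYP705A12: on WT root arrays their signals were at most 1.69% of that of THAS1 and 6.41% of that of THAD. On each pdx1.3 root array the signal was above what that share of the relative gives, by 19.83 to 22.99 times for MRN1 and 2.99 to 3.69 times for CYP705A12. MRN1 was called absent on the WT root arrays, so its share rests on signals not told from background and its ratios are not exact. For CYP71A16 this was not tested. No other technical explanation was tested, so a biological difference stays a hypothesis.

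Other groupings of the same arrays were fitted in the same way. For 3 against 3 arrays there are 10 groupings, the real one included, too few for a share under 0.05: in leaves the real count was 1650 and the highest other 0, in roots 184 and 5, and for WT leaves against WT roots 11949 and 0. With lists, again over 10 groupings, the real number was 10 in leaves and the highest other 10, and 9 in roots and the highest other 10. At least as many lists passed in 2 groupings in leaves and 3 in roots, the real one included. The number of lists that passed therefore does not set the real grouping apart. For calls in the same direction in both organs, 1 of 100 groupings drawn, the real one, reached 25, with 2 as the highest other. As the other groupings called 0 genes in leaves and at most 5 in roots, a shared count near 0 was fixed in advance, and these groupings say nothing on chance for the shared calls. For the interaction, 4 of 100 groupings, the real one included, reached 429, and the highest other gave 908. The 3 other groupings that large all kept the leaf groups and regrouped the roots, as did 12 in all (177 to 908), while the 87 that regrouped the leaves gave 0 to 33. This points to a structure of the samples, the leaf change itself, so these groupings do not exclude chance for the interaction.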

How the results depend on the processing

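The filter on present calls, the actin covariate and the fit without the 2 leaf arrays numbered 1 were tests chosen after the data were seen; the others were planned. PDX1.3 was lower in the mutant in both organs under every setting run (without 1 array, log2 -4.02 to -3.69 in leaves and -1.48 to -1.27 in roots). Of 89 named genes called, all kept their call under quantile normalization and under centring, 17 lost it with a constant of 1, 10 with the replicate block and 3 with the actin covariate. With arrays of 1 organ 39 of 79 lost it. There fewer arrays estimate the variance, and the spreads of leaves and roots are not pooled. Pooling can understate the SE in leaves: AT3G28270 had log2 values of 5.27, 6.83 and 7.67 in WT leaves and 4.01, 4.12 and 4.03 in WT roots. How much each adds was not tested. Of 19 list calls, 17 were lost with an estimated correlation, leaving 0 in leaves and 2 in roots, and 3 under quantile normalization. No called gene or list changed direction. The interaction and the comparison of WT organs could not be run with arrays of 1 organ. The filter on dim probe sets was set at the 25th percentile of signal, so that 17059 of 22746 passed by construction. Under it all 88 called named genes that remained kept their call, and 1 of 19 list calls was lost.

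The leaf count of 1650 was 515 with arrays of 1 organ, 976 with the replicate block, 480 at 2-fold, 651 at an adjusted p under 0.01 and 1053 to 1672 without 1 array. The root count of 184 was 78 with a constant of 1, 61 with arrays of 1 organ, 90 with the replicate block, 101 at 2-fold, 80 at an adjusted p under 0.01 and 75 to 385 without 1 array. The interaction count of 429 was 248 with a constant of 1, 134 with the replicate block and 137 to 554 without 1 array. The WT organ count stayed within 1.5 times of 11949 under each setting run other than stricter thresholds (5808 at 2-fold). The 25 calls shared by the organs were 14 with a constant of 1, 38 without dim probe sets, 4 with arrays of 1 organ, 6 with the replicate block, 39 with the filter on present calls, 40 without the 2 leaf arrays numbered 1, and 5 to 47 without 1 array. Fewer arrays or stricter thresholds account for part of this by construction; for the constant, the block and the other settings the cause was not tested. The replicate numbers were not found to pair the arrays: residuals of arrays with the same number in the same organ correlated at r = -0.242 to 0.017 and in the same genotype at -0.219 to 0.436.

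Some results that were not called changed direction, and the cause was not tested. For lists the direction is that of camera and the value the median. Without the 2 leaf arrays numbered 1, values in leaves were -0.24 for PDX1.2, 0.08 for auxin synthesis, 0.0688 for auxin response, 0.0022 for iron, 0.22 for salicylate, 0.0117 for cell cycle and -0.009 for root stele, and in roots -0.0614 for ethylene. With the actin covariate they were -0.0103 for PDX1.2 in roots, -0.052 for salicylate in leaves and -0.0085 for pyridoxal phosphate enzymes in roots. With arrays centred they were 0.0162 for auxin synthesis and -0.0321 for pyridoxal phosphate enzymes in leaves and -0.0216 for root hairs in roots, and after quantile normalization 0.0273 for chlorophyll and 0.0396 for pyridoxal phosphate enzymes in leaves and 0.0366 for root hairs in roots. With arrays of 1 organ they were 0.0828 for auxin synthesis in leaves and -0.0614 for ethylene in roots. Without dim probe sets they were -0.17 for heat shock and 0.0438 for iron in leaves and -0.0779 for ethylene in roots, and with the filter on present calls -0.17 for heat shock, 0.054 for iron and 0.0143 for auxin response in leaves and -0.0601 for ethylene in roots. For pyridoxal phosphate enzymes in roots the value was 0.0346 with a constant of 64 and 0.0452 with the replicate block.

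Without 1 array, ranges that included a change of direction were, in leaves, -0.0547 to 0.28 for PDX1.2, 0.0231 to 0.11 for auxin synthesis, -0.0004 to 0.10 for auxin response, 0.0019 to 0.17 for heat shock, -0.10 to 0.0086 for chlorophyll, 0.0108 to 0.12 for iron, -0.18 to 0.16 for salicylate and -0.037 to 0.0721 for pyridoxal phosphate enzymes. In roots they were -0.23 to 0.0039 for PDX2, -0.15 to 0.0655 for PDX3, -0.11 to 0.0186 for PLR1, -0.0734 to 0.0072 for ethylene, 0.0083 to 0.12 for ABA, 0.027 to 0.18 for flavonoids, -0.0382 to 0.28 for glucosinolates, -0.0172 to 0.11 for pyridoxal phosphate enzymes, -0.081 to 0.23 for hypoxia and -0.41 to 0.23 for root hairs. The root hair list passed camera without WT roots replicate 1 (0.23, adjusted p = 0.00134) and without WT roots replicate 3 (-0.41, adjusted p = 1.64e-09). The number of lists that passed was 9 to 14 in leaves and 9 to 12 in roots without 1 array.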

Other observations

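All tests in this part were chosen after the calls were seen. The array's gene descriptions were searched for words shared by called genes, over 746 words that describe 10 to 300 of 21439 genes, with one-sided exact hypergeometric tests. These tests take genes as independent, though genes of a family can change together, so their p-values can be too small. In pdx1.3 leaves, genes for xyloglucan enzymes, which loosen and rebuild the cell wall, were lower. With the word xyloglucosyl 9 of 28 fell, where 0.73 would by chance (adjusted p = 1.81e-05). With the word xyloglucan 9 of 36 fell, where 0.94 would (adjusted p = 0.000102). Those with the word xyloglucosyl were XTH15 (-3.42), XTH24 (-1.15), XTH33 (-1.13), XTH16 (-1.04), XTH8 (-1.02), XTH9 (-0.94), XTH4 (-0.89), XTR6 (-0.84) and XTH30 (-0.77). Arabinogalactan proteins, glycoproteins of the cell wall, fell in 6 of 28 cases (adjusted p = 0.00905), among them AGP17 (-1.62), FLA13 (-1.60) and AGP26 (-1.16). Genes with the word potassium rose in 10 of 44 cases, where 2.07 would by chance (adjusted p = 0.00717), among them the potassium transporters KUP9 (1.00), KUP3 (0.86) and KUP6 (0.82). Dehydration genes rose in 7 of 22 cases (adjusted p = 0.00844), among them ERD10 (1.71), ERD7 (1.66) and ERD14 (1.09). Genes with the word oxygen, many of them cytochromes P450, rose in both organs: in leaves 26 of 218, where 10.24 would by chance (adjusted p = 0.00565), and in roots 11 of 218, where 1.06 would (adjusted p = 6.79e-06). Those in roots include the marneral genes CYP705A12 and CYP71A16 as well as CYP81D1 (1.69), CYP91A2 (1.08) and CYP94B1 (0.86). No word passed for genes that fell in roots by this test, where 24 had an unadjusted p under 0.05.

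The marneral and thalianol genes raised the hypothesis that genes called in roots lie next to each other on the chromosomes. Among 21150 measured genes, 13 neighbouring pairs were both called in roots, 5 of them in these clusters. The test left out the 7 genes of the clusters: 8 pairs remained among 167 called genes, where 10000 random sets gave a mean of 1.33 and a 95th percentile of 3 (permutation p = 1e-04, the smallest these sets can give). These pairs include ANNAT4 (1.38) with ANNAT3 (1.27), calcium-binding annexins. Neighbours in such pairs can have related sequences, and cross-hybridisation was tested only for MRN1 and CYP705A12. In leaves 149 pairs were called against a mean of 114.63 (permutation p = 8e-04).

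The hypothesis that the mutation changes the genes around PDX1.3 was also tested. Of the 40 nearest measured genes 2 were called in leaves, where 2.95 would by chance (Fisher's exact test, two-sided p = 0.767), and 0 by limma in roots, where 0.33 would (Fisher's exact test, two-sided p = 1). This argues against a local effect in leaves as large as a call of most neighbours.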
